A study of Rattus norvegicus and Mus musculus with 3 samples.

How the data were processed

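Total RNA was extracted from hippocampus with TRIzol, and 1 µg went into each library with the TruSeq RNA Library Prep Kit v2, per the labels' protocols. The 3 libraries are 1 wild-type mouse of the 3xTg-AD line, 1 Sham rat and 1 2VO rat, grouped by their titles. Whether RNA of several animals was pooled is not given in the sources used here. fastp 0.21.0, HISAT2 2.1.0 and DESeq2 and the builds GRCm39 and mRatBN7.2 are named per the submitters' processing notes, without their roles. The quantifier, the annotation and any filters are not given in the sources used here.

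Each deposited table holds 1 column of a normalized expression signal per gene, never negative and with 6 decimals, named for its group per the file headers. Its unit is not stated. The values resemble FPKM or TPM, but neither is named in the sources used here. They summed to 268889 in the mouse, 325636 in Sham and 333941 in 2VO. The tables listed 0 mitochondrially encoded genes, so the sums do not settle the unit. Whole reads could not be recovered from the low values, so the depth of each library is unknown and no counting interval or detection floor is given. A value of 0 is reported only as listed at 0, since genes used by every cell can fail to be estimated.

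The libraries were compared as deposited, without rescaling. For the rats the log2 ratio of 2VO to Sham was taken with 1 unit added to both values, which understates the differences of low genes, over genes with a mean of at least 1 unit. Genes at least 2-fold apart were counted. No test was run, because each group holds 1 library. The design had foreseen TMM scaling and counting intervals in case the tables held counts, and these were not used. For each of the 33 gene lists the median log2 ratio was placed among 10000 random lists of the same size, drawn within 20 bins of mean expression. A list stood apart when its median lay outside the central 95% of the random lists. This describes the 2 libraries and is no test of the conditions, since genes of a list vary together. With at least 3 measured members 31 lists were placed: 5 lay above the random lists, 3 below and 23 within, and 1.55 outside would be expected if the lists were random draws. The mouse and rat tables were joined by symbol, ignoring case, which gave 16251 shared symbols.

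The groups, gene lists, thresholds, alternatives and the rule for named genes were fixed before the data were examined. That rule takes the 12 highest and 12 lowest log2 ratios among genes with a mean of at least 5 units and a name that is not a model identifier, up to 4 measured members per list with the largest absolute log2 ratio, the measured sex-linked genes, Actb and Gapdh, and the 10 most abundant mouse genes. Some genes that this rule takes are not reported here. Other members of the lists are named as examples and were chosen after their values were seen. Of the rat names 20173 of 30438 matched a symbol of a RefSeq gene table for the assembly GRCr8, and 22294 a symbol or synonym. Of the mouse names 25731 of 34714 matched a GENCODE M21 symbol. Those references differ in build from the one named in the notes, so no coordinates are given. Model identifiers made up 11495 of the rat names, and 1587 of these were measured.

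The alternatives were upper-quartile and median-of-ratios scaling, 0.25 or 4 units added before the log, no filter or a mean of at least 5 units, scaling to the sum without the 50 most abundant genes, and centring on a lowess trend with expression (span 0.3). Counts without model identifiers were added after the data were seen. The calculation was tested on simulated data for 2VO against Sham over 13557 genes. It recovered 49 of 50 genes made 3-fold higher and 42 of 49 made 3-fold lower, and 50 of 50 and 47 of 47 at 6-fold. Of unchanged simulated genes 0 passed 2-fold, which the simulated spread fixed in advance. Its SD was 0.2 log2 units for every gene, with no added noise at low values. This check therefore does not show how many 2-fold differences between the real libraries are noise. For lists of 15 genes, 8% of 200 unchanged lists and 100% of 200 lists shifted by 0.3 lay outside the central 95%. Python 3.11.15 was used with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.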

Results

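Hippocampal RNA was profiled in 3 libraries, 1 per group. The mouse library came from a 6 month old wild-type animal of the 3xTg-AD line, a mouse model of Alzheimer's disease that carries human transgenes in its transgenic members. The rat libraries came from animals of 3 to 4 months, 1 labelled Sham and 1 labelled 2VO. The series concerns models of Alzheimer's disease and of vascular dementia; the libraries here hold the 2VO model, its Sham control and a wild-type mouse. In this field 2VO usually denotes occlusion of both common carotid arteries, a model of lowered blood flow to the brain, and Sham denotes surgery without occlusion. Transgenic 3xTg-AD mice were not analysed here, so the mouse library had no partner of its own species. The mouse table listed 34714 genes, of which 24001 were above 0 and 12767 reached 1 unit. Both rat tables listed 30438 genes, with 22338 above 0 in Sham and 21985 in 2VO, and 13484 and 13586 at 1 unit or more. The 10 most abundant genes held 3.34% of the summed values in the mouse, 4.30% in Sham and 4.16% in 2VO. The values are normalized expression values in a unit the sources used here do not state, so the depth of each library is unknown. With 1 library per group no difference below has a replicate check, and every comparison describes these libraries, not the conditions.

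The main comparison set the 2VO rat beside the Sham rat, to ask how hippocampal transcripts differ with the vascular model. By their list medians, astrocyte reactivity genes, microglial genes and interferon-stimulated genes were lower in the 2VO library, while myelin, ependymal and cholinergic genes were higher. Whether the 2 dissections held equal shares of white matter and ventricular wall was not tested. Most members of each of these lists differed by less than 1.5-fold, and each list had members that went the other way. Gfap, the intermediate filament of reactive astrocytes, was 778 units in Sham and 360 in 2VO. Most other genes lay close together in both rats. Across 13550 genes with a mean of at least 1 unit, the log2 ratio of 2VO to Sham, with 1 unit added to both values, had a median of 0.04 and an SD of 0.24. Its central 95% ran from -0.41 to 0.50. Pearson's r of the log2 values across genes was 0.989 and Spearman's rho 0.988; genes are not independent replicates. At least a 2-fold difference was seen for 33 genes higher and 27 lower in 2VO, or 24 and 20 among the 11963 genes that carry more than a model identifier. At 1.5-fold the counts were 205 higher and 131 lower, a share of 61.0% higher. That share became 48.9% (159 higher and 166 lower) when the libraries were scaled to equal upper quartiles, so the excess of higher genes rests on the scaling.

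**Figure D1:**
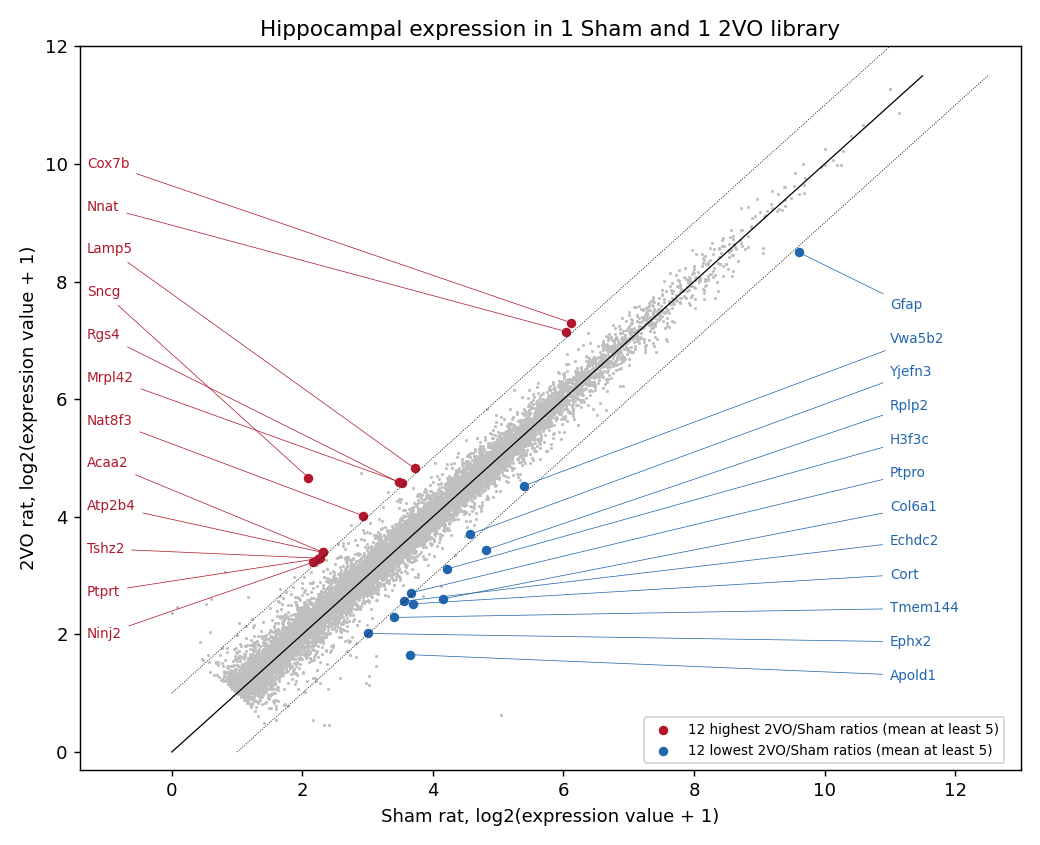
Expression of each measured gene in the Sham rat (horizontal axis) and the 2VO rat (vertical axis), both as log2 of the value plus 1 unit, with 1 library per group. Grey points are the 13550 genes with a mean of at least 1 unit, the solid line marks equality and the dotted lines a 2-fold difference; coloured points are the 12 highest and 12 lowest ratios among named genes with a mean of at least 5 units, from Sncg at 2.58 to Apold1 at -2.00.

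Reactive astrocyte genes had the lowest median of the 31 lists fixed beforehand and placed. Of 14 measured members 13 were lower in 2VO, 6 of them by at least 1.5-fold, and the median log2 ratio was -0.48, below all 10000 random gene lists matched for size and expression. Lcn2, a secreted lipocalin made by reactive astrocytes, was 4.28 units in Sham and 0.372 in 2VO. Hspb1, a small heat shock protein, was 7.78 and 1.75, and Timp1, an inhibitor of matrix metalloproteinases, was 3.55 and 1.39. Serpina3n was 2.33 and 0.754, and Aspg was 2.096 and 0.834. Vim, another intermediate filament gene, was the 1 member higher in 2VO, at 19.7 and 21.8. The median was closer to 0 in some settings, at -0.25 without a filter on low values or over the 5 members with a mean of at least 5 units, and at -0.28 with 4 units added before the log. In the remaining settings it was further from 0, down to -0.56 with 0.25 units added. General astrocyte markers did not move with them: 7 of 15 were higher and 8 lower, with a median of -0.011, within the random lists. Among these S100b was 487 in Sham and 556 in 2VO, Aldoc, a glycolytic aldolase, was 302 and 379, and Slc4a4, a bicarbonate transporter, was 20.6 and 17.8.

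Microglial genes were also lower in 2VO, in 12 of 17 measured members. Their median of -0.21 lay below all the matched random lists. The complement genes C1qa and C1qc were 39.3 and 15.3 units in Sham and 25.6 and 9.04 in 2VO, and Aif1, which encodes the microglial marker Iba1, was 23.8 and 13.5. The list did not move as a block, since P2ry12, a purinergic receptor of surveying microglia, was 5.49 in Sham and 8.83 in 2VO. Of 16 interferon-stimulated genes 13 were lower in 2VO, with a median of -0.25, again below all the random lists. Ifit3 was 2.04 and 0.460, the immunoproteasome gene Psmb8 was 4.53 and 2.51, and Bst2 was 5.46 and 3.14. Ifi27 went the other way, at 40.3 and 64.7. With 4 units added before the log the interferon median was -0.15. Lower in 2VO along with these groups were the T cell and antigen presentation genes Cd3e, at 7.15 and 1.20, Cd4, at 3.83 and 1.25, Cd74, at 7.35 and 3.86, and RT1-Da, at 1.81 and 0.687, chosen after the data were seen. Genes of disease-associated microglia were divided, 7 higher and 7 lower, with a median of 0.0077 and a mean of -0.09. Spp1 was 2.04 and 0.669, Gpnmb was 6.30 and 3.70, and Timp2 was 36.5 and 50.6. Only 6 of 19 cytokine and inflammatory signalling genes were measured, and their median of -0.12 was within the random lists. It lay below them, at -0.09 in both settings, over all 19 genes without a filter (percentile 0.06) and over the 6 with 4 units added before the log. Nfkbia, an inhibitor of NF-kB that its pathway induces, was 7.38 and 5.20.

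Oligodendrocyte and myelin genes were higher in 2VO in 16 of 17 measured members. The median of 0.33 was above all the random lists, though only Ermn, at 32.1 in Sham and 51.1 in 2VO, passed 1.5-fold. Mobp was 420 and 606, Mal was 83.7 and 123, and Sox10, a transcription factor of the lineage, was 20.8 and 30.5. The abundant myelin gene Mbp was 2051 in Sham and 2467 in 2VO. Olig1 was the 1 lower member, at 68.8 and 62.3. Oligodendrocyte precursor genes had a median of 0.14, within the random lists, with Cacng4 at 13.4 and 16.1. Ependymal genes, many of them components of motile cilia, were higher in 7 of 8 members with a median of 0.44, above all the random lists. Tmem212 was 1.31 and 2.72, Ak7 was 0.826 and 1.76, and Ccdc153 was 1.82 and 3.09. With 4 units added before the log the ependymal median was 0.26. Choroid plexus genes stood at a median of 0.32, percentile 98.7, but only 4 of 15 were measured. Ttr, the transthyretin gene and the main choroid plexus transcript, was 0.434 in Sham and 4.75 in 2VO. Without a filter on low values the choroid plexus median was 0.019, at percentile 75.1 and within the random lists. Whether the 2VO dissection held more white matter, ventricular wall or choroid plexus than the Sham dissection was not tested. The myelin, ependymal and choroid plexus differences therefore cannot be assigned to the hippocampus itself. Genes of the cholinergic system were higher in 7 of 8 members with a median of 0.23, percentile 99.2, though none passed 1.5-fold. The measured members were receptor genes and Ache. Chat, Slc18a3 and Slc5a7 did not reach a mean of 1 unit and were left out. The nicotinic receptor subunits Chrna4 and Chrnb2 were 2.28 and 14.0 in Sham and 3.81 and 18.9 in 2VO, and the muscarinic receptor gene Chrm4 was 5.69 and 8.30.

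**Figure D2:**
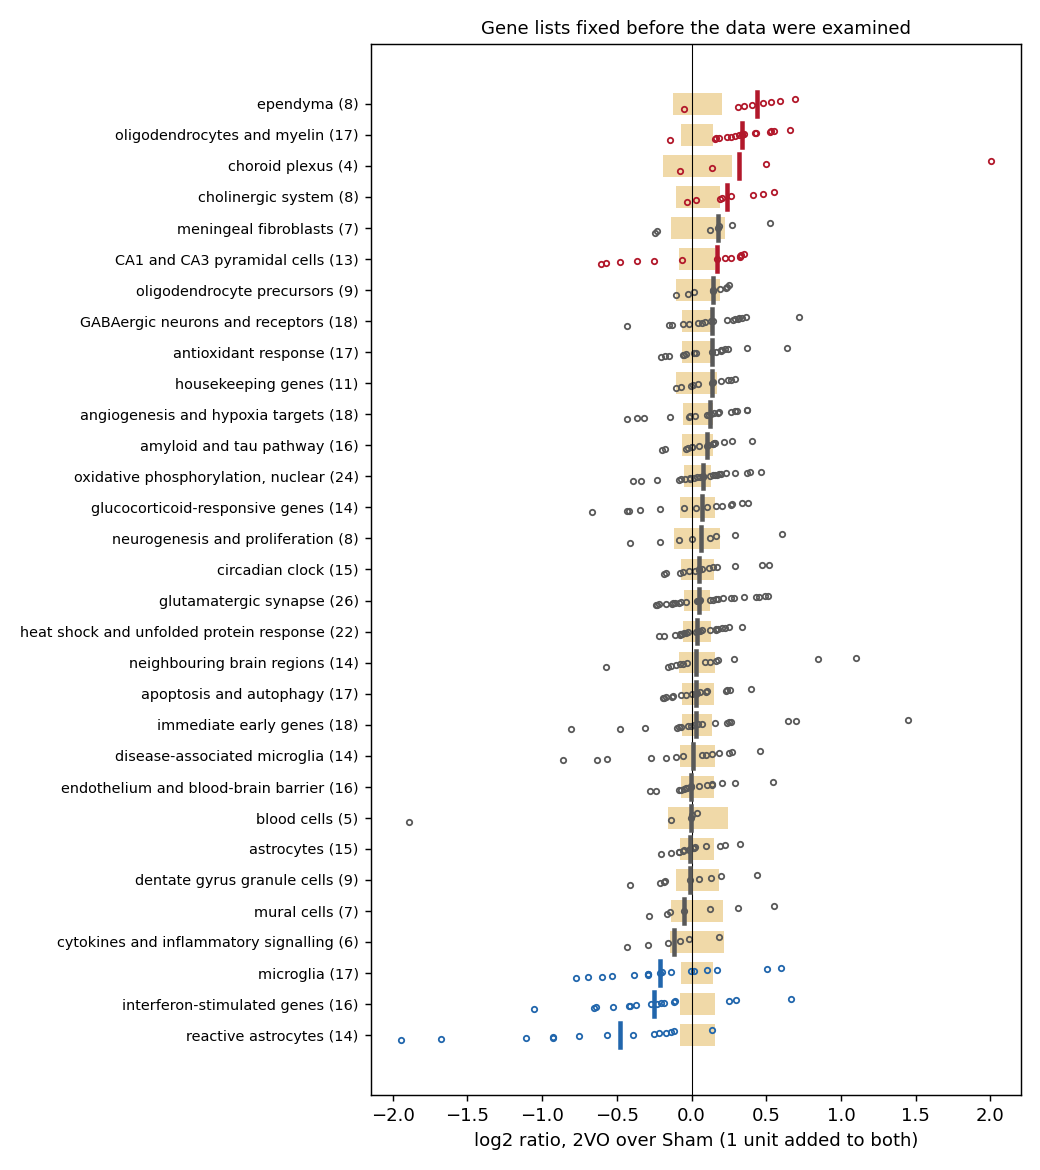
Log2 ratio of 2VO to Sham, with 1 unit added to both values, for the members of 31 gene lists. Open circles are single genes, thick bars the list medians and shaded bands the central 95% of 10000 random lists of the same size and expression; red lists (5) have medians above the band, blue lists (3) below it and grey lists (23) within it, and the number of measured genes stands beside each name.

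**Figure D3:**
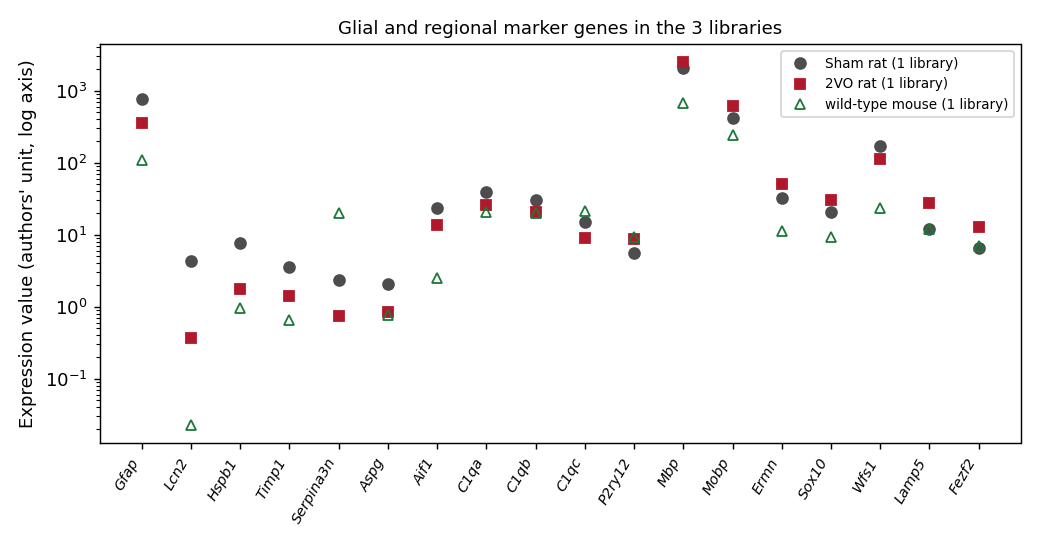
Expression values of marker genes in the Sham rat, the 2VO rat and the wild-type mouse, 1 library each, on a log axis in the deposited unit. From left to right the genes mark reactive astrocytes, microglia, oligodendrocytes, pyramidal neurons (Wfs1) and cortical neurons (Lamp5, Fezf2); Gfap is 778 in Sham, 360 in 2VO and 110 in the mouse, and Lcn2 is 4.28, 0.372 and 0.023.

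Neuronal genes showed divided differences. Pyramidal cell markers of CA1 and CA3 had a median of 0.17, percentile 98.5, and a mean of -0.03; 7 genes were higher and 6 lower. The members furthest from 0 were lower in 2VO. Wfs1, an endoplasmic reticulum protein enriched in CA1, was 169 and 111, Rgs14, enriched in CA2, was 55.0 and 36.7, Pou3f1 was 34.7 and 24.6, and Bok was 48.2 and 37.1. This list turned to -0.16, percentile 0.28 and below the random lists, over the 10 members with a mean of at least 5 units, and to -0.06 without a filter, so it has no settled direction. Granule cell markers of the dentate gyrus had a median of -0.013, with Calb1 at 25.6 and 35.0 and Stxbp6 at 33.4 and 24.8. The 26 glutamatergic synapse genes had a median of 0.05 and none passed 1.5-fold. The vesicle release genes Syt1, Syn1 and Snap25 were 198, 118 and 454 in Sham and 282, 166 and 614 in 2VO. GABAergic genes had a median of 0.14, just inside the random lists at percentile 97.4. Calb2, the calretinin gene, was 3.44 and 6.29, and Npy was 19.9 and 14.5. Immediate early genes, which neuronal activity induces, had a median of 0.03. Npas4, Egr1 and Fos were 0.502, 19.9 and 4.03 in Sham and 3.11, 33.0 and 6.86 in 2VO, while Btg2 was 12.7 and 6.84. Amyloid and tau pathway genes had a median of 0.11, with Bace1, the beta-secretase, at 25.3 and 33.8 and Psenen, a gamma-secretase subunit, at 54.0 and 65.5. Markers of neighbouring brain regions had a median of 0.03, yet the cortical genes Lamp5 and Fezf2 were 12.2 and 6.62 in Sham and 27.3 and 12.7 in 2VO. The other measured cortical genes of the list differed less: Rorb was 3.13 and 4.04, Cux2 3.62 and 3.92 and Tbr1 13.04 and 12.52. Over the 4 members with a mean of at least 5 units the median was 0.40, above the random lists, but it is the midpoint between Tbr1 at -0.05 and Fezf2 at 0.85, and Tbr1 and Ppp1r1b were lower in 2VO. Neurogenesis and proliferation genes had a median of 0.06, with Neurod2 at 76.3 and 57.1.

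Vascular and metabolic lists all lay within the random lists. Endothelial and blood-brain barrier genes had a median of -0.00084, with Itm2a at 10.9 and 16.3 and Vwf at 2.30 and 1.72. Mural cell genes stood at -0.05, with Tagln, a smooth muscle gene, at 5.13 and 7.99. Angiogenesis and hypoxia targets had a median of 0.12, with 12 of 18 higher. Bnip3 was 44.5 and 58.0 and Egln3, an oxygen-sensing hydroxylase, was 5.11 and 6.89, whereas Ankrd37 was 3.21 and 2.13 and Hk2 was 2.104 and 1.41. Nuclear genes of oxidative phosphorylation had a median of 0.08, with Cox5b at 137 and 189 and Cox6c at 196 and 149. The tables listed 0 mitochondrially encoded genes. Antioxidant genes stood at 0.14, with Gstm1, a glutathione transferase, at 73.7 and 115. Heat shock and unfolded protein response genes stood at 0.04, with Herpud1 at 15.1 and 19.4 and Hspa5, a chaperone of the endoplasmic reticulum, at 95.9 and 82.3. Apoptosis and autophagy genes stood at 0.03, with Lamp2, a lysosomal membrane protein, at 23.7 and 31.6. Glucocorticoid-responsive genes had a median of 0.07 and a mean of -0.03, with the metallothionein gene Mt2A at 73.4 and 45.9. Circadian clock genes stood at 0.05, with Ciart at 2.29 and 3.72 and Nr1d1 at 24.1 and 33.8. Meningeal fibroblast genes stood at 0.18, with Dcn, the decorin gene, at 4.23 and 6.51. Blood cell genes had a median of -0.0030, and the haemoglobin genes Hba1 and Hbb were 168 and 107 in Sham and 153 and 107 in 2VO. Haemoglobin gene copies share sequence, so their single values are uncertain. Cd3e, a T cell receptor component in that list, was 7.15 and 1.20. The medians of the astrocyte, endothelial and mural lists differed in sign from their means of 0.02, 0.04 and 0.05. Housekeeping genes had a median of 0.13, with Actb at 987 and 985 and Gapdh at 1031 and 1219. Among the sex-linked genes, Eif2s3y was 25.3 in Sham and 23.9 in 2VO and Kdm5d was 6.42 and 6.14; both are Y-linked.

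Among single genes with a mean of at least 5 units and leaving out model identifiers, Sncg, which encodes gamma-synuclein, had the highest ratio, at 3.26 in Sham and 24.4 in 2VO, a log2 ratio of 2.58. Next came Cox7b, a subunit of cytochrome c oxidase, at 68.3 and 157, the imprinted gene Nnat at 65.0 and 141, Lamp5 as given above, and Rgs4, a regulator of G protein signalling, at 10.2 and 23.0. Atp2b4, a plasma membrane calcium pump, was 3.96 and 9.52, and Acaa2, an enzyme of fatty acid oxidation, was 3.97 and 9.55. Nat8f3 was 6.65 and 15.2, Ninj2 was 3.48 and 8.36, Mrpl42 was 10.5 and 22.9, Ptprt was 3.74 and 8.78 and Tshz2 was 3.81 and 8.82. At the other end, Apold1, an immediate early gene of endothelium, was 11.6 in Sham and 2.15 in 2VO, a log2 ratio of -2.00. The model identifier LOC100362027, named after its values were seen, lay below it, at 31.9 and 0.540. Col6a1, a collagen chain, was 16.8 and 5.07, the ribosomal protein gene Rplp2 was 27.3 and 9.86, and the neuropeptide gene Cort was 11.99 and 4.74. Tmem144 was 9.60 and 3.88, the histone gene H3f3c was 17.6 and 7.65, Echdc2 was 10.8 and 4.92, and Ephx2, an epoxide hydrolase, was 7.05 and 3.04. Ptpro was 11.7 and 5.53, Yjefn3 was 22.8 and 12.03 and Vwa5b2 was 41.1 and 22.1. How reads shared between near-identical gene copies were assigned is not given in the sources used here, so the values of Cox7b, Mrpl42, Rplp2 and H3f3c, which belong to gene classes with such copies, are given with that reservation; it was not tested for these genes singly. Mrps28, picked out after its values were seen, was listed at 0 in Sham and at 4.17 in 2VO.

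The wild-type mouse library, which is not itself a disease model, was set beside the rats as levels only. Species, age and annotation all differ, as does sex by the sex-linked genes. Its most abundant genes were Fth1, the ferritin heavy chain, at 1313 units, Eef1a1 at 1051, Cpe at 1028, Calm2 at 937 and Aldoa at 864, followed by Apoe at 826, Tmsb4x at 804, Cst3 at 780 and Camk2a at 699. Of the 50 most abundant genes in the mouse, 38 were among the 50 of the Sham rat, while the 2 rats shared 44. Across 11436 shared symbols with a mean of at least 1 unit over mouse and Sham, Spearman's rho between mouse and Sham was 0.866. Over the same genes rho was 0.876 between mouse and 2VO. The 2VO values did not enter that filter, so the difference between the 2 coefficients is not read as greater likeness. Each describes genes, which are not independent. Glutamatergic synapse genes ranked high in each animal, with median rank percentiles of 97.1 in the mouse, 96.2 in Sham and 96.0 in 2VO. Reactive astrocyte genes ranked at 8.07 in the mouse, 22.5 in Sham and 9.22 in 2VO, so by this median the Sham rat was the highest of the 3 libraries. Their member Serpina3n went the other way, at 20.2 units in the mouse, 2.33 in Sham and 0.754 in 2VO. Oligodendrocyte genes ranked at 81.5 in the mouse and at 92.1 and 92.0 in the rats, with Mbp at 682 units in the mouse. Microglial genes ranked at 48.1, 53.2 and 44.3. App, the amyloid precursor protein gene, was 373 in the mouse, 423 in Sham and 468 in 2VO, and Apoe was 2255 in Sham and 1864 in 2VO. The choroid plexus and blood cell lists, with 3 members each, ranked furthest apart, at 29.0 and 8.24 in the mouse against 0.909 and 38.7 in Sham. In 2VO they ranked at 26.1 and 34.6, so the choroid plexus gap to the mouse was particular to Sham. Several haemoglobin names had no partner in the other species. Hba-a1, which had one, went the other way, at 58.1 in the mouse and 6.25 in Sham. Neither the choroid plexus gap nor the blood cell gap is read as a species difference. Among single genes, Gapdh was 6.36 in the mouse against 1031 in Sham, and S100b was 40.3 against 487, while Mt1, a metallothionein, was 212 against 9.70. A Gapdh value this low in brain limits what single values say across the species. The sex-linked genes differed between the mouse and the rats too. Y-linked Eif2s3y and Kdm5d, present in both rats, were listed at 0 in the mouse, where Xist, the X-inactivation transcript, was 58.4 units. That is the pattern of female RNA in the mouse library and male RNA in both rat libraries. Sex therefore differed along with species, and the 2 cannot be told apart here.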

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

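The unknown depth and the single library per group limit every result here, and no alternative replaces a replicate. The counts of genes at least 2-fold apart, 33 higher and 27 lower in 2VO, became 74 and 54 with 0.25 units added, 8 and 10 with 4 units added and 17 and 10 at a mean of at least 5 units. The amount added shrinks or widens the ratios of low genes, and the higher minimum takes fewer genes. Under upper-quartile scaling the counts were 28 and 33, of which 28 and 27 were among the original genes. The rank correlation of mouse and Sham moved from 0.866 to 0.934 without a filter and to 0.790 at a mean of at least 5 units. The pyramidal cell list reversed to -0.16 at a mean of at least 5 units; the cause was not tested beyond the smaller number of members. Of the list medians under the alternatives, 233 kept their direction or stayed within the random lists, 8 moved outside and 2 moved inside. The GABAergic list moved above in 3 settings, the cytokine list below in 2, and the hypoxia, antioxidant and neighbouring region lists above in 1 each. Reactive astrocytes ranged from -0.56 to -0.25, microglia from -0.29 to -0.15, interferon-stimulated genes from -0.34 to -0.15, oligodendrocytes from 0.28 to 0.34 and the cholinergic list from 0.18 to 0.25, each outside the random lists in all 8 settings. For single named genes 0 reversed, 28 values dropped below their fold threshold and 21 passed it. No paired analysis was possible because each group holds 1 library. Centring on gene length and GC content was not run, since these values were not used here for the rat.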

Other observations

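The tests in this part and the 3 added gene lists were chosen after the main results were seen. The tests of astrocyte number and of exchanged libraries use values already seen, while that of cortical genes uses values not seen before and that of ribosomal genes had 1 member, Rplp2, seen before. Neuropeptide genes, a list that shares Sst, Npy, Cck and Vip with the GABAergic one, were lower in the 2VO library in 11 of 19 measured members, with a median log2 ratio of -0.09 at percentile 0.78 of the matched random lists. That place rests on genes seen before the list was made: without Cort, Cartpt and the 4 shared genes, 7 of 13 were lower and the median was -0.03, at percentile 13.5 and within the random lists. Cartpt, which encodes the CART peptides, was 4.03 units in Sham and 0.375 in 2VO, Cort was 11.99 and 4.74, and Nmb was 10.3 and 6.75. Others went the other way: Grp, gastrin-releasing peptide, was 4.16 and 8.60, Pdyn, prodynorphin, was 21.8 and 29.7, and Penk was 9.78 and 13.4.

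Only 4 of 13 genes of T cells and antigen presentation reached a mean of 1 unit, and all 4 were lower in 2VO, with a median of -0.94. Cd3e was 7.15 in Sham and 1.20 in 2VO, Cd4 was 3.83 and 1.25, Cd74, the invariant chain of class II molecules, was 7.35 and 3.86, and RT1-Da, a class II gene of the rat, was 1.81 and 0.687. The list was made after Cd3e and Cd4 had been seen, so these are not independent of the choice, and the 2 others are too few to place.

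Reactive astrocyte genes stood lower in the 2VO library together with microglial and interferon-stimulated genes, although gliosis is often described in models of lowered blood flow to the brain. Fewer astrocytes in the 2VO sample would lower the general astrocyte markers as well. Their median was -0.011, above the upper quartile of the reactive list at -0.18 and within the random lists. Both values were known when this comparison was set, so it is no independent test of that explanation. It shows only that the general markers did not fall with the reactive genes in these 2 libraries. An exchange of the Sham and 2VO libraries cannot be told apart from the labels as given: both rats had 2 of the 3 listed Y-linked genes, Eif2s3y and Kdm5d, at 1 unit or more and Ddx3y below it, at 0.073 in Sham and 0.043 in 2VO, and the labels give no property other than the model that differs between them. A reaction to surgery in the Sham animal and variation between individual animals stay open and were not tested, since each group holds 1 library.

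Lamp5 and Fezf2, markers of cortical neurons, were higher in the 2VO library, at 27.3 and 12.7 units against 12.2 and 6.62, as the 2 highest members of their list, whose other measured cortical genes had log2 ratios of 0.29 for Rorb, 0.09 for Cux2 and -0.05 for Tbr1. More neighbouring cortex in the 2VO dissection could account for the first pair. In a second list of cortical markers, whose values had not been seen, 9 of 11 measured genes were higher and the median of 0.12 stood at percentile 87.9 of the random lists. That is short of the upper bound set for the explanation and above the median of all genes, 0.04, so added cortex cannot be told apart from its absence. The 2 members lowest in Sham had the highest ratios, Rprm at 1.33 and 2.51 units and Syt6 at 1.26 and 1.87; cortical levels were not used here, and a difference in the hippocampal neurons themselves was not tested.

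Several genes with large ratios, such as Rplp2 at 27.3 and 9.86 units, encode ribosomal or mitochondrial proteins, and reads divided between near-identical gene copies may account for them. Across 81 cytosolic ribosomal protein genes the median distance of the log2 ratio from that of all genes was 0.21, against 0.13 in matched random lists with a central 95% from 0.099 to 0.165, at percentile 99.99. Without Rplp2 the median over 80 genes was again 0.21, at percentile 100. Ratios ran from -1.38 for Rplp2 to 0.75 for Rpl30, so the genes did not all move in the same direction. The median of the signed ratios was -0.07, against 0.04 for all genes, and was not placed among random lists. Without Rplp2, 33 of 80 genes were higher and 47 lower in 2VO. A shared shift downward would widen the distance too and was not tested. Short transcripts can also vary more between libraries, which was not tested, and the test does not cover the mitochondrial protein genes.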
